A study of Mus musculus with 12 samples.

How the data were processed

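The series holds 12 RNA sequencing libraries of CD4 T cells sorted by flow cytometry from mouse kidneys, 3 in each of 4 groups: WT control, WT after ischemia-reperfusion injury (IRI), Keap1 KO control and Keap1 KO after IRI. Per the labels' protocols, mononuclear cells were enriched on Percoll before sorting, 1 ng of total RNA entered a stranded total RNA kit for very small inputs, and paired reads of 36 bp were made over 2 lanes of a NextSeq 500. IRI was 30 min without blood flow to both kidneys, with harvest at 24 h. The labels do not say whether control mice had sham surgery, how Keap1 was deleted, or whether the libraries of a group came from different animals, so p-values measure the spread between these libraries. No batch or date that separates the libraries is given.

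Per the file headers, the deposited table holds 1 FPKM value (fragments scaled for transcript length and for the fragments of the library) per gene and library, for 52632 genes. The submitters' processing notes name bcl2fastq 2.17.1.14, TopHat2 2.1.0, Cufflinks 2.2.1, Partek 7.0 and the mouse build GRCm38 without saying what each was used for. The annotation release, the strand setting and any scaling between libraries are not stated. Of the gene IDs, 52399 were paired with a symbol and 52485 matched GENCODE mouse release 21, which gave gene types and GRCm38 coordinates. Where a symbol occurred more than once (74 further genes), the gene with the highest mean kept it and the others kept their ID. FPKM gives no counts, so the depth of each library is unknown and no counting error can be attached to a value. An FPKM of exactly 0 can be a failed estimate, since the abundant transcript Malat1 was listed at 0 in KO control 1, and such genes are described only as listed at 0.

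Values were used as deposited. Genes with a mean of at least 1 FPKM over the 12 libraries were tested (19288 genes, 12065 of them protein-coding). Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), with 1 mean per group, all 12 libraries in 1 fit and 8 residual degrees of freedom before moderation. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and every adjusted p of a gene comes from this test. Fold changes are differences on the log2(FPKM + 1) scale, which understates the change of genes with low values, and their errors are standard errors (SE). The 7 comparisons were IRI against control in WT, IRI against control in KO, KO against WT in controls, KO against WT after IRI, the genotype by IRI interaction, IRI against control averaged over genotype, and KO against WT averaged over condition.

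A rescaling by median ratios was run beside the values as deposited. Each library was divided by the median of its ratios to the geometric mean over the 16018 tested genes above 0 in all libraries. It is called the rescaled value where given, and changes between genotypes are led by it because the median gene differed between genotypes.

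Gene lists were written from general knowledge before the data were examined, and 31 were used: NRF2 targets, glycolysis and hypoxia, oxidative phosphorylation, immediate early genes, T cell activation and costimulation, inhibitory receptors, naive and central memory, trafficking receptors, Th1, Th2, Th17, regulatory T cell, interferon stimulated, NF-kB and inflammatory, cell cycle, heat shock, unfolded protein and amino acid stress, p53 and apoptosis, T cell identity, proximal tubule, loop and distal tubule, injured tubule, endothelium, fibroblast and pericyte, macrophage and monocyte, neutrophil, dendritic cell, B cell, CD8 T and NK cell, erythroid and platelet, and mitochondrial mRNA. Lists with at least 5 tested members were tested against all other genes with camera (limma) at a preset correlation of 0.01, adjusted over lists within a comparison. The same test was repeated with the correlation estimated from the data, and fry (limma) tested whether a list's genes moved on balance 1 way. Members were also counted with p-values adjusted over the list alone, always from the values as deposited. The endothelium, fibroblast and pericyte, and erythroid and platelet lists had fewer tested members and were only counted. Some genes stand in more than 1 list, such as Cxcr3 and Ctla4.

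The genes named were chosen by a rule fixed before the data were examined. In each comparison these are the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, leaving out predicted genes and, for comparisons of 2 groups, genes whose groups overlap. Up to 4 members of each list past the threshold with the smallest adjusted p are added. Where fewer than 10 genes passed, the 5 with the smallest p in each direction are added as values that did not pass, and Keap1, Nfe2l2 and 7 NRF2 targets are named in every comparison of genotypes. Outside this rule, where 5 or fewer genes passed, all of them are named whatever their symbol. Other genes named outside this rule are said to have been chosen after their values were seen.

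The level of 1390 chemosensory receptor genes (olfactory, vomeronasal and trace amine receptors), which have no known role in T cells, was used as a measure of background. Group differences in such library measures were tested with exact two-sided permutation tests over the 924 ways to split 12 libraries into groups of 6. The limma step was tested on simulated data built from the real means and spread. For IRI against control in WT it recovered 14% of 100 genes changed by a log2 of 1 and 58% of 100 changed by a log2 of 2 among 19288 genes, with 0 false calls. A simulated unchanged comparison of the KO groups called 0 genes, with 5.03% of unadjusted p-values under 0.05. In these simulations each gene varied independently, with no shift or correlation shared by the genes of a library. They therefore cannot show how often false calls arise in the real libraries.

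Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, a minimum mean of 5 FPKM or no minimum, quantile normalization, median-ratio rescaling, rescaling of each library to a common sum over the tested genes, no trend, robust moderation (with statmod 1.5.0), weights per library (arrayWeights), a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Further alternatives were chosen after the data were seen: leaving out 3 libraries that stand apart (KO control 1, WT control 3 and WT IRI 3), the level of the receptor genes as a covariate, and protein-coding genes only. The 3 libraries were picked without a numerical rule. WT control 3 and WT IRI 3 had the lowest summed FPKM (859343 and 739969), while KO control 1 correlated with KO control 3 at 0.878, the highest of any pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All columns of the table were used.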

Results

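Gene expression was measured by total RNA sequencing in CD4 T cells sorted from the kidneys of 12 samples, 3 in each of 4 groups. WT mice were bought C57BL/6J animals and the mice lacking Keap1 in CD4 T cells (KO) were bred in house on the same background, so genotype and source of mice cannot be separated. Keap1 holds the transcription factor NRF2 (encoded by Nfe2l2) at low levels, and its loss is known to raise NRF2 target genes. The IRI groups were collected 24 h after 30 min of ischemia of both kidneys, and the labels do not say whether the controls had sham surgery. The values are FPKM, so the depth of each library is unknown. Because the labels do not say that replicates are separate animals, p-values measure the spread between these samples.

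The summed FPKM of a library ran from 739969 to 2089551, and the 3 most abundant genes took 17.7% to 63.1% of it. Between 16059 and 20000 genes had at least 1 FPKM. Libraries of the same group correlated at a Spearman coefficient of 0.756 to 0.878 across genes, against 0.719 to 0.850 for libraries of different groups. Genes for olfactory and other chemosensory receptors, 1390 in all and not known to act in T cells, averaged 1.19 ± 0.166 FPKM in WT and 0.750 ± 0.320 in KO (SD, n = 6; exact permutation test, two-sided, p = 0.00433). Their mean was 0.265 in KO control 1 and 0.431 in KO control 3, against 0.876 to 1.41 elsewhere. The abundant transcript Malat1 was listed at 0 in KO control 1. The mitochondrial ribosomal RNA mt-Rnr1 was listed at 0 in WT IRI 1 and 2 and in KO control 1 and 2. It was also at 0 in KO IRI 1, 2 and 3, and at 47800 to 78270 FPKM in the other libraries. Such zeros are no sign of absence, and those of mt-Rnr1 fell unevenly over the groups. Genes of small nucleolar RNAs summed to 601132 FPKM in KO control 1 and to at most 166319 in any other library. Igkc, an antibody light chain, reached 1261 FPKM in KO control 1, against 7.16 to 254 elsewhere.

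Keap1 (chromosome 9, 21229730 to 21239361, GRCm38) was present in every library. It read 8.50, 9.00 and 9.87 FPKM in WT control, 8.80, 6.31 and 6.03 in WT IRI, 6.61, 5.75 and 7.77 in KO control, and 6.28, 5.95 and 4.59 in KO IRI. Averaged over condition its log2 difference between KO and WT was −0.34 ± 0.13 (SE, n = 6, adjusted p = 0.0945), or −0.61 ± 0.11 after rescaling by median ratios (adjusted p = 0.0484). The labels do not name the deleted part of the gene, and a value for the whole gene can include transcripts that lack an exon, so Keap1 alone does not check the labels. Nqo1, a quinone reductase and classical NRF2 target, separated the genotypes. It was 6.85, 4.87 and 7.75 FPKM in KO control and 6.90, 3.38 and 4.80 in KO IRI. It was at most 0.543 in any WT library, with WT control 3 and WT IRI 3 listed at 0.

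**Figure D1:**
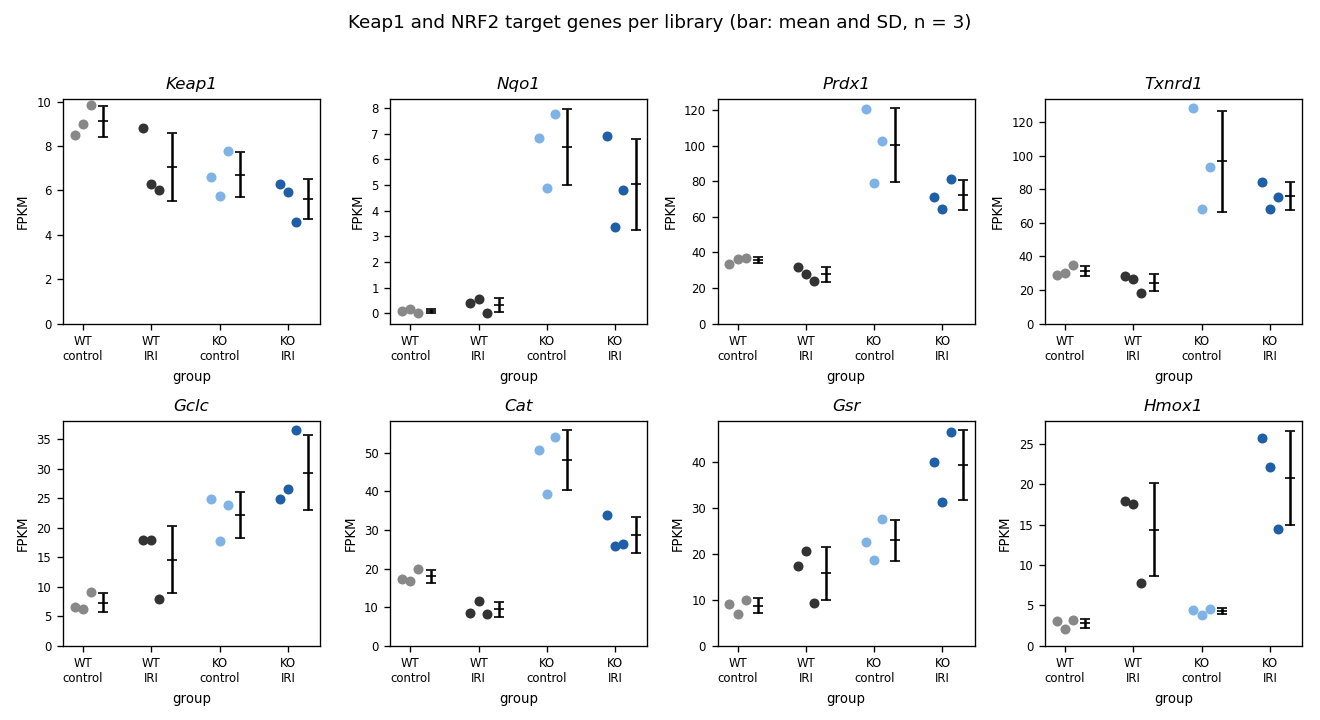
FPKM of Keap1 and 7 NRF2 target genes in each of the 12 libraries (points), with the mean and SD of each group of 3. All 6 KO libraries lie above all 6 WT libraries for Nqo1, Prdx1, Txnrd1 and Cat.

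The genotypes were compared without IRI by setting KO control against WT control, a difference that includes the source of the mice. Both protein-coding genes past the threshold as deposited were NRF2 targets. Nqo1 rose by a log2 of 2.55 ± 0.26 after rescaling (SE, n = 3, adjusted p = 0.00592). Prdx1, a peroxide-reducing enzyme, rose by 1.12 ± 0.12 (adjusted p = 0.00704), from 35.6 ± 1.73 to 100.5 ± 20.9 FPKM (SD). Txnrd1, which recycles thioredoxin, rose by 1.21 ± 0.15 after rescaling (adjusted p = 0.0196), while its value as deposited did not pass (adjusted p = 0.109). Rescaled values lead here because the median of all tested genes was higher in KO, by a log2 of 0.299 in controls, 0.255 after IRI and 0.292 averaged over condition as deposited, and 0.0142, 0.019 and 0.0353 after rescaling.

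In this comparison 2 of 32 NRF2 targets rose, 0 fell and 30 did not pass, and 20 were higher adjusted over the list alone. The list was shifted up against all other genes (adjusted p = 3.78e-09 by camera, adjusted p = 0.609 with an estimated correlation), with a median log2 of 0.844 as deposited and 0.533 rescaled, and above 0 under each scaling. Cat (catalase, 1.03 ± 0.15 rescaled, adjusted p = 0.0627), Gclc (1.17 ± 0.24, 0.220) and Gclm (1.02 ± 0.35, 0.309), which build glutathione, and Srxn1 (1.22 ± 0.58, 0.478) were higher without passing. Hmox1 (0.23 ± 0.26, 0.770), Slc7a11 (−0.80 ± 0.28, 0.323) and Nfe2l2 itself (0.31 ± 0.23, 0.654) did not pass either. Further T cell lists stood higher with 0 members past the threshold over all genes. These were naive and central memory genes (12 of 15 higher adjusted over the list alone, adjusted p = 2.62e-05), T cell identity genes (6 of 19, adjusted p = 0.000101), Th17 genes (5 of 10, adjusted p = 0.01) and T cell activation genes (2 of 19, adjusted p = 0.0409, and 0.208 after rescaling). Each had an adjusted p of 0.609 with an estimated correlation. Quantile normalization ended the call of the T cell identity list (adjusted p = 0.443) and that of the T cell activation list (0.726), whose median became −0.00795. Th1 genes had a median of −0.106 (0 of 12 past over all genes, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.075, adjusted p = 0.609 with an estimated correlation). They were called lower after rescaling (median −0.425, adjusted p = 0.0102) and after quantile normalization (adjusted p = 0.000343). Antigen-presenting cell lists moved up as well. The dendritic cell list (6 of 12 higher adjusted over the list alone, 0 past over all genes, adjusted p = 0.00977) and the macrophage and monocyte list (3 of 19, 0 over all genes, adjusted p = 0.00309) were also higher in KO controls (adjusted p = 0.609 for each with an estimated correlation). The loop and distal tubule list (0 of 8 past over all genes or the list alone, median −0.502, adjusted p = 0.0271) and the neutrophil list (0 of 11, median 0.018, test downward, adjusted p = 0.0291) were called lower. Each had an adjusted p of 0.609 with an estimated correlation and was not called after rescaling (0.119 and 0.131).

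In all, 5 genes were higher and 0 lower as deposited by limma, and 6 and 1 after rescaling. At an unadjusted p under 0.05 there were 4022 genes as deposited and 2129 after rescaling. The other 3 genes past the threshold as deposited had larger differences. They were Gm20658 (log2 4.29 ± 0.43, an antisense RNA, at a mean of 23.9 FPKM in KO controls and 0.208 in WT controls), and Gm33707 (4.09 ± 0.34, a processed pseudogene on chromosome 3). The third was the small nucleolar RNA Gm25744, listed at 0 in all 3 WT controls. Reads of such genes can belong to an overlapping or near-identical gene. The count of 5 became 7 (4 higher, 3 lower) without WT control 1, 22 (6 higher, 16 lower) without WT control 3, 9 without WT IRI 3, 9 without KO control 1 and 1961 without KO control 2. It was 31 (11 higher, 20 lower, 2 of them shared) without WT control 3, WT IRI 3 and KO control 1, the set picked after the data were seen as standing apart.

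After injury, KO IRI was set against WT IRI to see whether the genotypes differed in the injured kidney. NRF2 targets were again higher. After rescaling, Nqo1 rose by a log2 of 2.05 ± 0.26 (SE, n = 3, adjusted p = 0.0232), Cat by 1.23 ± 0.15 (0.0217), Prdx1 by 1.06 ± 0.12 (0.0203) and Txnrd1 by 1.32 ± 0.15 (0.0203), the last without passing as deposited (0.0516). Klrc1, an inhibitory receptor of NK cells and some T cells, fell by 2.93 ± 0.34 (adjusted p = 0.0210), from 17.4 ± 4.19 to 1.94 ± 1.09 FPKM (SD, n = 3). Trim59 rose by 1.37 ± 0.19 (0.0443). Trat1 and Dusp4, which adjust T cell receptor signalling, and Cst7, a protease inhibitor, passed as deposited (adjusted p = 0.0416, 0.0309 and 0.0370) and not after rescaling (0.0593, 0.0693 and 0.0536).

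Of 32 NRF2 targets, 3 rose, 0 fell and 29 did not pass as deposited, 4 rose rescaled, and 19 were higher adjusted over the list alone (adjusted p = 9.71e-07, adjusted p = 0.394 with an estimated correlation). Their median log2 of 0.752, or 0.496 rescaled, was above 0 under each scaling. T cell identity genes were higher with a median of 0.968, or 0.672 rescaled (17 of 19 adjusted over the list alone, 0 over all genes, adjusted p = 3.41e-10, adjusted p = 0.394 with an estimated correlation). Th17 genes (6 of 10, adjusted p = 0.000691), trafficking receptors (10 of 20, adjusted p = 0.000148) and oxidative phosphorylation genes (18 of 33, adjusted p = 5.63e-06) were higher as deposited, adjusted over the list alone. They had 0 members past over all genes, as deposited or rescaled, and an adjusted p of 0.394 each with an estimated correlation. Neutrophil markers (0 of 11 past over all genes or the list alone, adjusted p = 0.000148) and CD8 T and NK cell markers (0 of 13 over all genes, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.0193) were lower. Each had an adjusted p of 0.394 with an estimated correlation. The CD8 T and NK cell list was not called after quantile normalization (0.149) or with each library scaled to a common sum (0.0886).

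The 11 genes past the threshold were 10 higher and 1 lower as deposited, and 9 and 2 after rescaling. An unadjusted p under 0.05 was held by 4324 genes as deposited and 3179 after rescaling. The count was 0 without WT control 1, 1 without WT IRI 1, 1 without WT IRI 2, 8 (3 higher, 5 lower) without WT IRI 3, 17 without KO control 1, 552 without KO control 2 and 6 without KO IRI 3. It was 19 (4 higher, 15 lower, 1 shared) without the 3 libraries that stand apart, and limma called 0 genes with a pseudocount of 5 and 0 with each library scaled to a common sum.

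Averaging over condition used all 12 libraries to measure the mean difference between KO and WT. It is the mean of the control and IRI comparisons above, so it is no independent evidence beside them. NRF2 targets were higher in this mean, with rescaled log2 rises of 2.30 ± 0.18 for Nqo1 (SE, n = 6, adjusted p = 0.000572), 1.27 ± 0.10 for Txnrd1 (0.000677), 1.13 ± 0.10 for Cat (0.00141), 1.09 ± 0.08 for Prdx1 (0.000542) and 0.96 ± 0.17 for Gclc (0.0443). Cd4 itself rose by 1.30 ± 0.14 (adjusted p = 0.00484), from 95.2 to 280 FPKM in controls. Klrc1 fell by 2.64 ± 0.24 (0.00127), Klrc2 by 1.70 ± 0.21 (0.0116), Klrk1 by 1.49 ± 0.22 (0.0296) and Klre1 by 1.42 ± 0.22 (0.0297). Il12rb2, part of the receptor for the Th1-inducing cytokine IL-12, had a log2 difference of −0.84 ± 0.19 as deposited (adjusted p = 0.0316, and 0.0318 after rescaling).

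As deposited, 19 of 32 NRF2 targets rose, 0 fell and 13 did not pass, and 9 rose after rescaling. Adjusted over the list alone, 24 were higher and 1 lower (adjusted p = 4.79e-08, adjusted p = 0.496 with an estimated correlation). Rescaled rises outside the rule for named genes, chosen after their values were seen, were Gsr (glutathione reductase, 1.01 ± 0.16, adjusted p = 0.0318), Ftl1 (ferritin light chain, 0.82 ± 0.12, 0.0232), Txn1 (thioredoxin, 1.36 ± 0.21, 0.0297) and Abcc1 (a conjugate exporter, 0.83 ± 0.15, 0.0453). Gclm (0.81 ± 0.25, 0.102), Srxn1 (1.31 ± 0.41, 0.110), Hmox1 (0.25 ± 0.18, 0.464) and Slc7a11 (−0.72 ± 0.20, 0.0886) did not pass after rescaling. Nfe2l2 mRNA did not pass on either scale (rescaled 0.31 ± 0.16, 0.306).

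Most T cell lists were higher in KO in this average, with direction unchanged under each scaling for those that follow. Of 19 T cell identity genes, 16 rose and 3 did not pass as deposited and 4 rose rescaled, Cd4, Cd5 (0.84 ± 0.14) and Lat (0.58 ± 0.09) among them. Adjusted over the list alone, 18 were higher (adjusted p = 4.79e-08, adjusted p = 0.496 with an estimated correlation). Naive and central memory genes had 13 of 15 higher as deposited (14 adjusted over the list alone) and 1 rescaled, the neuronal vesicle gene Nsg2 at 0.86 ± 0.15 (adjusted p = 3.19e-05, adjusted p = 0.496 with an estimated correlation). Th17 genes had 6 of 10 higher as deposited (7 adjusted over the list alone) and 2 rescaled (adjusted p = 0.00133, adjusted p = 0.496 with an estimated correlation). Ccr6, a chemokine receptor of Th17 cells, rose by 1.79 ± 0.32 and Tmem176a by 1.29 ± 0.22 after rescaling, while Il17a (1.33 ± 0.31, 0.0616) passed only as deposited. Th1 genes had medians of −0.0169 as deposited and −0.317 rescaled, with 3 higher and 1 lower of 12 as deposited and 3 and 2 adjusted over the list alone (adjusted p = 0.401, adjusted p = 0.751 with an estimated correlation). They were called lower after quantile normalization (adjusted p = 0.0171) and not after rescaling (0.101). Costimulatory Tnfrsf4 (OX40, 0.81 ± 0.13) and Tnfsf8 (0.67 ± 0.12) rose, in a list with 6 of 19 higher as deposited and 12 adjusted over the list alone (adjusted p = 0.00128, adjusted p = 0.496 with an estimated correlation). Gzmb, a cytotoxic protease, rose by 1.86 ± 0.29 in the CD8 T and NK cell list, where 2 genes rose, 1 fell and 10 did not pass. That list was lower by its test (adjusted p = 0.0436, adjusted p = 0.496 with an estimated correlation) and its median (−0.160), with a mean of 0.00397, and was not called after quantile normalization (0.0918) or with each library scaled to a common sum (0.1). Neutrophil markers were lower (median −0.427, 0 of 11 past over all genes or the list alone, adjusted p = 0.000709, adjusted p = 0.496 with an estimated correlation). Antigen-presenting cell lists had medians above 0 beside the T cell lists, at 0.419 for dendritic cell and 0.518 for macrophage and monocyte genes as deposited. By camera their adjusted p was 0.0246 and 0.114 after quantile normalization, and 0.015 for each with each library scaled to a common sum.

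Antibody and T cell receptor segments were among the largest differences as deposited, higher in KO. They included Ighj2 (listed at 0 in all 6 WT libraries), Traj33 (6.29 ± 1.28), Igha (4.26 ± 1.02) and Jchain (3.07 ± 0.70), of which only Ighj2 passed after rescaling (adjusted p = 0.0400). As deposited 2299 genes were higher and 340 lower (87.1% higher), against 73 and 33 (68.9%) after rescaling, 35 and 19 (64.8%) after quantile normalization and 7 and 6 (53.8%) with each library scaled to a common sum. The total of 2639 became 34, 51 and 534 without WT control 1, 2 and 3, and 1131 and 412 without WT IRI 2 and 3. It became 60, 5898 and 45 without KO control 1, 2 and 3, and 107, 1045 and 292 without KO IRI 1, 2 and 3. It was 54 (23 higher, 31 lower, 30 shared) without the 3 libraries that stand apart.

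**Figure D2:**
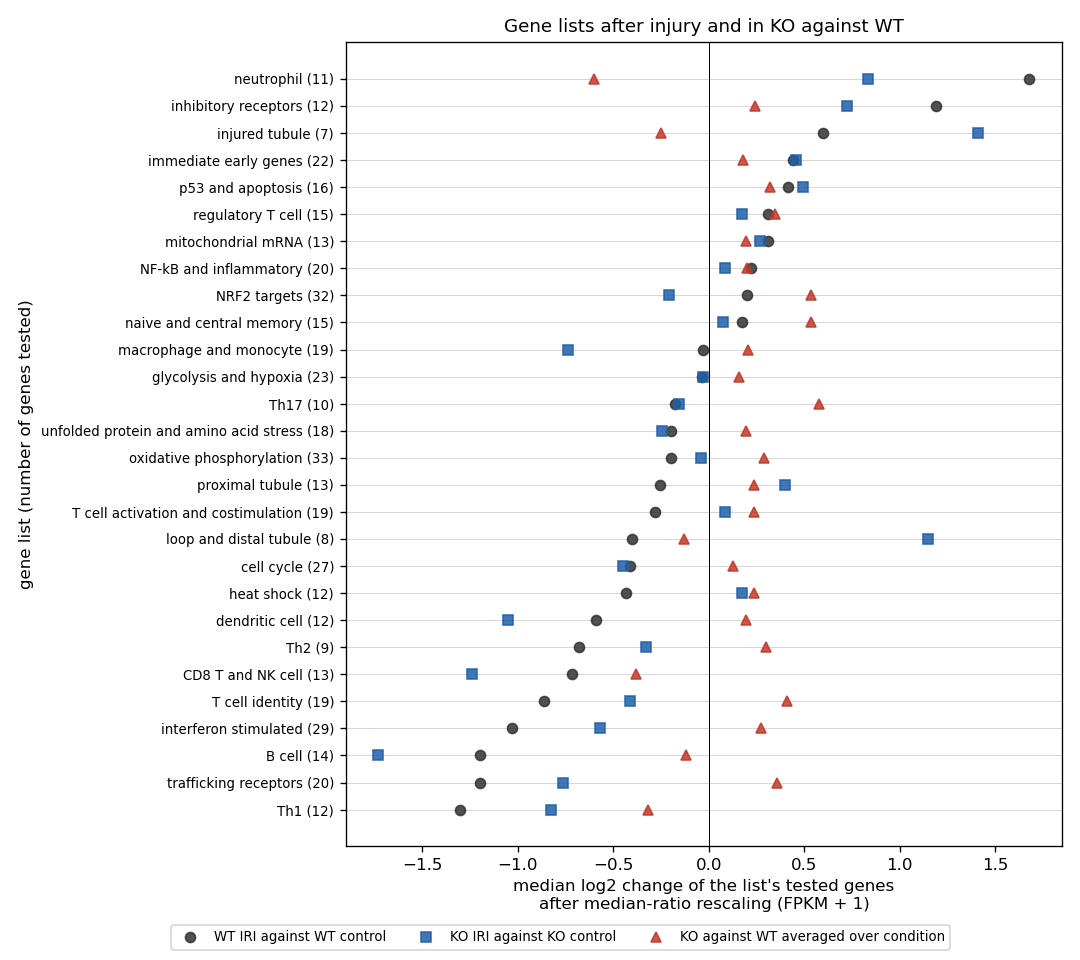
Median log2 difference of the tested members of 28 gene lists after median-ratio rescaling, for IRI against control in WT and in KO and for KO against WT averaged over condition. The NRF2 target median is 0.537 for KO against WT, and the Th1, trafficking, interferon and T cell identity medians lie below 0 after IRI in both genotypes.

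The mean response to injury was measured as IRI against control averaged over WT and KO. Such an average can be moved by either genotype alone and does not show that both changed. Zfp683, a transcription factor of tissue-resident lymphocytes known as Hobit, fell by a log2 of 4.00 ± 0.21 (SE, n = 6, adjusted p = 2.19e-05), and Xcl1, a chemokine for dendritic cells, by 3.24 ± 0.20 (7.37e-05). Cxcr6, a homing receptor, fell by 2.46 ± 0.19 (0.000142), and Tbx21, which encodes the Th1 regulator T-bet, by 1.94 ± 0.13 (7.37e-05). The inhibitory receptor genes Ctla4 and Tigit rose by 1.49 ± 0.17 (0.00073) and 1.34 ± 0.17 (0.00127). Genes that injured tubules can express rose as well, with Spp1 at 5.34 ± 0.92 (0.00553), Thbs1 at 4.50 ± 0.45 (0.000348) and Lcn2 at 4.22 ± 0.68 (0.0040). The metallothioneins Mt1 and Mt2, which bind metal ions, rose by 3.25 ± 0.49 (0.00294) and 3.88 ± 0.75 (0.0102). Fold changes from here on are as deposited, since the median of all genes moved by less than 0.1 between IRI and control except with each library scaled to a common sum (−0.329 in KO and −0.150 averaged).

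**Figure D3:**
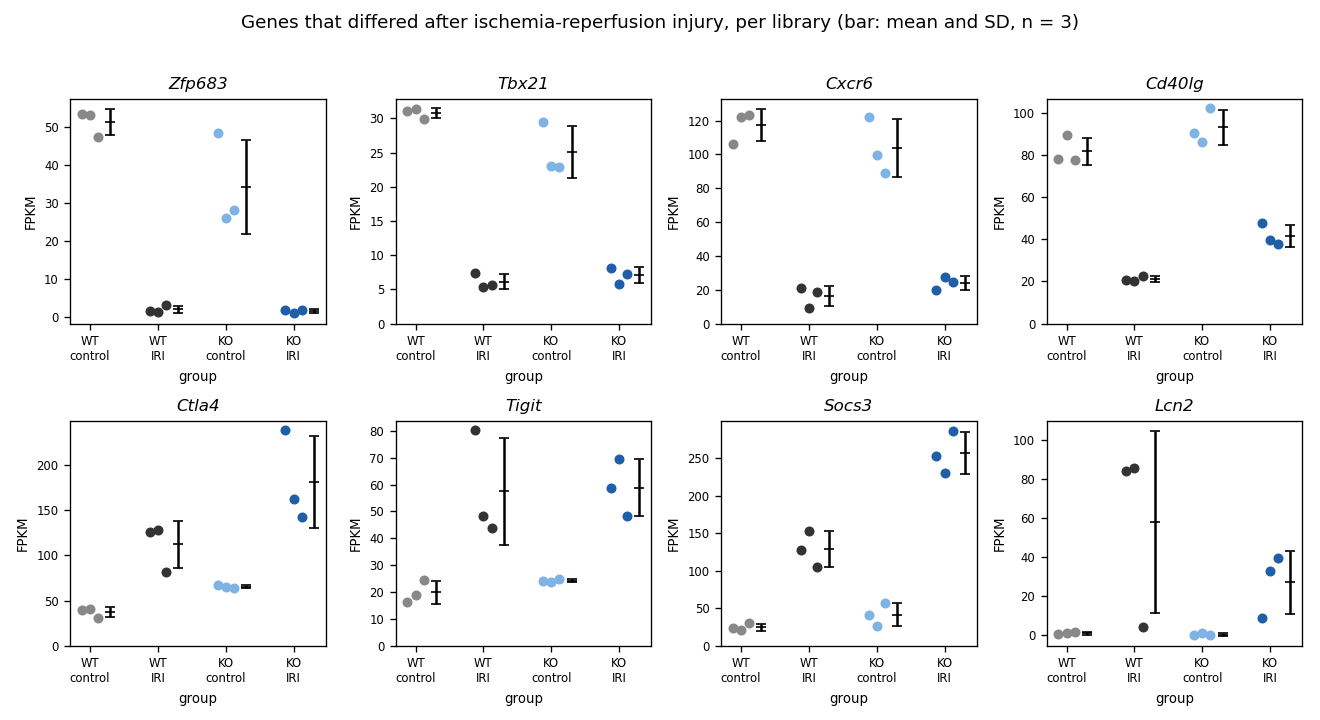
FPKM of 8 genes in each of the 12 libraries (points), with the mean and SD of each group of 3. Zfp683, Tbx21, Cxcr6 and Cd40lg are lower after IRI in both genotypes, while Ctla4, Tigit, Socs3 and Lcn2 are higher.

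The Th1, trafficking receptor, interferon stimulated and T cell identity lists fell. Of 12 Th1 genes, 7 fell, 0 rose and 5 did not pass, and 9 fell adjusted over the list alone (adjusted p = 1.95e-08), with Tbx21 and Il12rb1 (−1.68 ± 0.22) as examples. Trafficking receptors had 11 of 20 lower (13 adjusted over the list alone, adjusted p = 2.21e-09), including Itga1 (−1.83 ± 0.16) and Cxcr3 (−1.78 ± 0.18). Among 29 interferon stimulated genes, 18 fell (24 adjusted over the list alone, adjusted p = 5.93e-14), such as Oas3 (−1.54 ± 0.17), Xaf1 (−1.23 ± 0.15) and Bst2 (−1.70 ± 0.25). T cell identity genes had 12 lower, 1 higher and 6 not passing (15 lower and 1 higher adjusted over the list alone, adjusted p = 5.68e-11), with Cd3g at −1.76 ± 0.15, Lck at −1.27 ± 0.18 and Cd5 at −1.18 ± 0.17. These 4 lists had an adjusted p of 0.246 each with an estimated correlation. Cell cycle genes had 8 of 27 lower (10 adjusted over the list alone, adjusted p = 2.71e-05, adjusted p = 0.390 with an estimated correlation), including Top2a (−0.89 ± 0.18) and Mki67 (−0.92 ± 0.21). Unfolded protein genes had 5 of 18 lower (5 adjusted over the list alone, adjusted p = 0.00605, adjusted p = 0.459 with an estimated correlation), chaperones such as Pdia4 (−1.16 ± 0.13) and Calr (−0.78 ± 0.12). Of 33 oxidative phosphorylation genes 0 passed over all genes or the list alone, with a median of −0.246 (adjusted p = 0.0128, adjusted p = 0.800 with an estimated correlation).

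The inhibitory receptor, p53 and apoptosis, and immediate early lists rose. Inhibitory receptors had 6 higher and 3 lower of 12 (7 and 3 adjusted over the list alone, adjusted p = 0.00303, adjusted p = 0.390 with an estimated correlation). Btla rose by 1.31 ± 0.18, with Entpd1, the ectonucleotidase CD39, at −1.25 ± 0.16. Genes of p53 and apoptosis had 4 higher and 1 lower of 16 (9 and 2 adjusted over the list alone, adjusted p = 0.000417, adjusted p = 0.266 with an estimated correlation), including Cdkn1a (2.15 ± 0.23) and Bcl2l11 (1.46 ± 0.16). Immediate early genes had 3 of 22 higher, Fosl2, Zfp36 (1.09 ± 0.18) and Ier3 (1.51 ± 0.30), and 7 higher and 3 lower adjusted over the list alone (adjusted p = 0.000406, adjusted p = 0.507 with an estimated correlation).

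Markers of other cells moved beside these groups. B cell genes had 10 of 14 lower (14 adjusted over the list alone, adjusted p = 5.09e-10, adjusted p = 0.246 with an estimated correlation), with Ighm at −1.60 ± 0.18. CD8 T and NK cell genes had 9 of 13 lower (11 adjusted over the list alone, adjusted p = 7.32e-11, adjusted p = 0.111 with an estimated correlation), with Nkg7 at −2.34 ± 0.20 and Gzma at −1.52 ± 0.23. Dendritic cell genes had 6 of 12 lower (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.000135, adjusted p = 0.266 with an estimated correlation), with H2-Ab1 at −1.68 ± 0.28. The macrophage and monocyte list had 5 lower and 2 higher of 19 (6 and 2 adjusted over the list alone, adjusted p = 0.0128, adjusted p = 0.674 with an estimated correlation). Its median was −0.845 in KO and −0.085 in WT, where camera did not call it (adjusted p = 0.666). Averaged over genotype, Ccr2 of this list fell by 1.40 ± 0.19, while Cd14 (1.66 ± 0.33) and Chil3 (2.39 ± 0.49) rose. Neutrophil markers had 7 higher and 1 lower of 11, the same adjusted over the list alone (adjusted p = 0.000215, adjusted p = 0.266 with an estimated correlation), with S100a8 at 2.52 ± 0.43 and Mmp9 at −2.21 ± 0.18. Injured tubule genes had 2 of 7 higher (3 adjusted over the list alone, adjusted p = 0.000135, adjusted p = 0.266 with an estimated correlation). Spp1 ran from 35.6 to 307 FPKM in the IRI libraries except KO IRI 1 (7.85), against at most 7.48 in controls.

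The remaining lists were not called in this average. NRF2 targets had 5 higher and 4 lower of 32 (8 and 7 adjusted over the list alone), with a median of −0.160, a mean of 0.0619 and a test upward (adjusted p = 0.855). Hmox1, which degrades heme, rose by 1.98 ± 0.22 and Cat fell by 0.80 ± 0.14. T cell activation genes had 4 higher and 7 lower of 19, the same adjusted over the list alone (adjusted p = 0.256), with Tnfrsf9 (1.65 ± 0.26) higher and Cd40lg (−1.53 ± 0.11), the ligand that helps B cells, lower. The NF-kB list had 5 higher and 4 lower of 20 (9 and 6 adjusted over the list alone, adjusted p = 0.321), with Birc3 (1.27 ± 0.16) higher and Tnf (−1.84 ± 0.16) lower. Regulatory T cell genes had 3 higher and 4 lower of 15 (5 and 5 adjusted over the list alone, adjusted p = 0.395), with Ikzf4 (1.66 ± 0.15) and Il10 (1.20 ± 0.22) higher. Glycolysis genes had 2 higher and 3 lower of 23 (2 and 4 adjusted over the list alone, adjusted p = 0.723), and Th2 genes 1 higher and 3 lower of 9 (1 and 4, 0.0834). Naive and central memory genes had 2 higher and 2 lower of 15, the same adjusted over the list alone (0.450). Their median was 0.0396 and their mean −0.00787, and the medians of the naive and central memory, NF-kB and mitochondrial mRNA lists fell below 0 with each library scaled to a common sum. Heat shock genes had 1 of 12 lower (1 adjusted over the list alone; 0.321), and Th17 genes 0 of 10 past the threshold (2 lower adjusted over the list alone; 0.481). The proximal tubule (13 genes; 0.989), loop and distal tubule (8 genes; 0.356) and mitochondrial mRNA (13 genes; 0.261) lists had 0 genes past it over all genes or the list alone. Of the lists too short to test, endothelium had 0 of 4 past it, fibroblast and pericyte 1 lower of 3 (2 adjusted over the list alone) and erythroid and platelet 0 of 4.

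In total 580 genes rose and 1164 fell after IRI (33.3% higher), against 1225 and 1414 (46.4%) after rescaling, 1170 and 1474 (44.3%) after quantile normalization and 200 and 806 (19.9%) with each library scaled to a common sum. The 1744 became 1121 without WT IRI 2, 1128 without KO control 3, 1044 without KO IRI 2 and 1151 without KO IRI 3. Without the 3 libraries that stand apart it was 1068 (550 higher, 518 lower, 840 shared).

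Within WT, the effect of injury was read from WT IRI against WT control. Zfp683 fell from 51.3 ± 3.41 to 1.93 ± 0.989 FPKM (SD, n = 3; log2 −4.21 ± 0.29 SE, adjusted p = 0.000462). Tbx21 fell by a log2 of 2.18 ± 0.18 (adjusted p = 0.000629), Cxcr3 by 2.34 ± 0.25 (0.00192) and Ly6c2, a surface protein of effector T cells, by 3.66 ± 0.31 (0.000629). Thbs1 rose by 5.01 ± 0.63 (0.0033), Lcn2, which injured tubules and neutrophils make, by 4.17 ± 0.96 (0.0397) and Ramp3, a receptor partner, by 3.21 ± 0.27 (0.000629). Ctla4 (1.56 ± 0.24, 0.00749) and Tigit (1.45 ± 0.24, 0.0107) rose, as did the heme oxygenase Hmox1 (1.96 ± 0.31, 0.00856).

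The lists named here had the directions of the average. Th1 genes had 6 of 12 lower (7 adjusted over the list alone, adjusted p = 3.01e-08) and trafficking receptors 10 of 20 (12, 1.79e-09). T cell identity genes had 10 of 19 lower (15 lower and 1 higher adjusted over the list alone, adjusted p = 2.66e-12), and CD8 T and NK cell genes 3 of 13 (7, 1.06e-07). Each of these 4 lists had an adjusted p of 0.269 with an estimated correlation. Interferon stimulated genes had 10 of 29 lower (21 adjusted over the list alone, adjusted p = 6.30e-14, adjusted p = 0.296 with an estimated correlation), among them Oas3 (−1.50 ± 0.24) and Zbp1 (−1.18 ± 0.21). Inhibitory receptors had 5 higher and 1 lower of 12 (8 and 3 adjusted over the list alone, adjusted p = 0.00336, adjusted p = 0.490 with an estimated correlation). Neutrophil markers had 2 higher and 1 lower of 11 (7 and 1 adjusted over the list alone, adjusted p = 0.000335, adjusted p = 0.447 with an estimated correlation), with Clec4d at 2.57 ± 0.29. B cell genes had 1 of 14 lower (4 adjusted over the list alone, adjusted p = 1.28e-05, adjusted p = 0.490 with an estimated correlation). Dendritic cell genes (0 of 12 over all genes or the list alone, adjusted p = 0.0344, adjusted p = 0.565 with an estimated correlation) were placed lower. Injured tubule genes had 1 of 7 higher (2 adjusted over the list alone, adjusted p = 0.00478, adjusted p = 0.490 with an estimated correlation).

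In WT 229 genes rose and 500 fell (31.4% higher), against 64 and 40 (61.5%) with each library scaled to a common sum. The 729 became 348, 301 and 274 without WT control 1, 2 and 3, 351 without WT IRI 1 and 255 without WT IRI 2. It was 628 (332 higher and 296 lower, 52.9% higher) without WT IRI 3 and 224 (126 higher, 98 lower, 154 shared) without the 3 libraries that stand apart.

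Within KO, KO IRI against KO control gave falls and rises in many of the same genes. Zfp683 fell by a log2 of 3.80 ± 0.29 (SE, n = 3, adjusted p = 0.000656), Xcl1 by 3.15 ± 0.29 (0.00192), Cxcr6 by 2.07 ± 0.27 (0.0086) and Tbx21 by 1.70 ± 0.18 (0.00405). Thbs1 rose by 4.00 ± 0.63 (0.0191), Socs3, a brake on cytokine signalling, by 2.66 ± 0.28 (0.00405), Hmox1 by 2.01 ± 0.31 (0.0189) and Ctla4 by 1.42 ± 0.24 (0.0269). Antibody segments fell from uneven control values, such as Igkv1-110 (−4.70 ± 0.91, 0.0478).

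Th1 genes had 2 of 12 lower (6 adjusted over the list alone, adjusted p = 7.08e-08, adjusted p = 0.208 with an estimated correlation). T cell identity genes had 2 of 19 lower (10 adjusted over the list alone, adjusted p = 4.86e-08, adjusted p = 0.277 with an estimated correlation), and interferon stimulated genes had 3 of 29 (12 adjusted over the list alone, adjusted p = 7.58e-11, adjusted p = 0.277 with an estimated correlation). B cell genes had 2 of 14 lower (14 adjusted over the list alone, adjusted p = 8.79e-13, adjusted p = 0.208 with an estimated correlation). CD8 T and NK cell genes had 3 of 13 lower (12 adjusted over the list alone, adjusted p = 8.79e-13, adjusted p = 0.0625 with an estimated correlation). Dendritic cell genes had 2 of 12 lower (8 lower and 1 higher adjusted over the list alone, adjusted p = 3.58e-07, adjusted p = 0.208 with an estimated correlation). Macrophage and monocyte genes had 1 of 19 lower (7 lower and 2 higher adjusted over the list alone, adjusted p = 6.42e-05, adjusted p = 0.419 with an estimated correlation). Neutrophil markers were placed higher with 1 higher and 1 lower of 11 (3 and 1 adjusted over the list alone, adjusted p = 0.00225, adjusted p = 0.419 with an estimated correlation). So were injured tubule genes (0 of 7, 3 adjusted over the list alone, adjusted p = 2.53e-05, adjusted p = 0.217 with an estimated correlation) and loop and distal tubule genes (0 of 8 over all genes or the list alone, adjusted p = 0.0322, adjusted p = 0.595 with an estimated correlation), the last not called after rescaling (0.106). The loop and distal tubule genes averaged 1.3, 8.32 and 45.2 FPKM in KO IRI 1, 2 and 3, against 0.93, 6.7 and 3.32 in KO control 1, 2 and 3, so KO IRI 3 stood far above the rest.

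Genes of p53 and apoptosis had 2 of 16 higher, Cdkn1a (1.94 ± 0.33) and Bcl2l11 (1.28 ± 0.23), and 5 adjusted over the list alone (adjusted p = 2.53e-05, adjusted p = 0.217 with an estimated correlation). Their median of 0.402 became −0.000826 with each library scaled to a common sum, where the median of all genes was −0.329 and the list was still called higher (adjusted p = 0.000632). NRF2 targets had 1 of 32 higher, Hmox1, and 5 higher and 2 lower adjusted over the list alone, with a median of −0.308, a mean of 0.0113 and a test downward (adjusted p = 0.707).

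In KO 63 genes rose and 104 fell (37.7% higher), against 6 and 46 (11.5%) with each library scaled to a common sum. The 167 became 88, 83 and 104 without WT control 1, 2 and 3, 91 and 92 without WT IRI 1 and 2, and 57, 848 and 57 without KO control 1, 2 and 3. It became 304, 44 and 58 (the last 33 higher and 25 lower, 56.9% higher) without KO IRI 1, 2 and 3, and 40 (15 higher, 25 lower, 29 shared) without the 3 libraries that stand apart.

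The injury responses of the genotypes share no library and were compared with each other. Their calls are not independent, since 1 fit of all 12 libraries gave each gene the same estimate of spread in both. Of the 729 genes called in WT, 708 changed in the same direction in KO (97.1%, against 67.3% of all genes), and of the 167 called in KO 162 had the same direction in WT. Called higher in both were 56 genes, with 0.748 given by independent lists, and called lower in both were 84, with 2.70. The numbers for independent lists can be too low here, because genes of low spread are favoured in both lists. Across all 19288 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.280. Over the 1744 genes called in the average, the median size of the log2 change was 0.989 in WT and 0.800 in KO. Of these, 1255 genes (72.0%) changed more in WT, a description without a test.

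**Figure D4:**
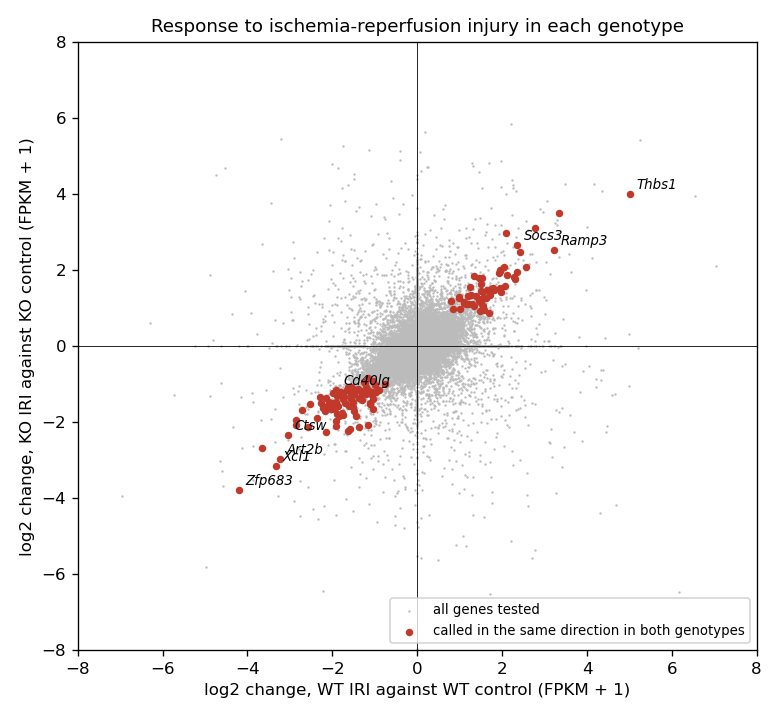
Log2 change after IRI in WT (horizontal) against KO (vertical) for each of 19288 tested genes, with genes called in the same direction in both genotypes in red. The axes end at 8 in both directions, and 7 genes, none of them called in both, lie beyond them.

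Whether injury acted differently in KO was tested by the interaction of genotype and IRI. The NRF2 targets showed no difference past the threshold: Nqo1 at a log2 of −0.59 ± 0.40 (SE, n = 3 per group), Gclc at −0.46 ± 0.42, and Gclm at −0.45 ± 0.49. Others were Txnrd1 at 0.07 ± 0.34, Srxn1 at 0.12 ± 0.80, Hmox1 at 0.05 ± 0.44 and Slc7a11 at 0.22 ± 0.36. The last were Nfe2l2 at −0.04 ± 0.42 and Keap1 at 0.12 ± 0.26. All had an adjusted p of 0.999. Genes with the smallest p in each direction, such as Dcun1d3 (1.12 ± 0.27) and Ntrk3 (−1.20 ± 0.25), did not pass either (0.999). The single gene past the threshold was Gm25744 (adjusted p = 0.00844), a small nucleolar RNA at 744, 109.5 and 195 FPKM in KO controls, 2.26e-05 in WT IRI 1 and listed at 0 in all other libraries. T cell identity genes (median 0.340, 0 of 19 past over all genes or the list alone, adjusted p = 0.000463) and heat shock genes (0.542, 0 of 12, 0.00226) were placed higher. Macrophage and monocyte (−0.669, 0 of 19; 0.000463), dendritic cell (−0.587, 0 of 12; 0.000763) and B cell (−0.702, 0 of 14; 0.00263) markers were placed lower. Each of these 5 lists had an adjusted p of 0.871 with an estimated correlation. With each library scaled to a common sum the median of all genes was −0.335 and that of the T cell identity genes, no longer called (0.196), −0.0918.

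By limma 0 genes were higher and 1 lower in the interaction, and 646 had an unadjusted p under 0.05. The count of 1 became 3, 4 and 12 (2, 2 and 11 of them higher) without WT control 1, 2 and 3, and 2, 2 and 3 without WT IRI 1, 2 and 3. It became 6, 3 and 3 without KO control 1, 2 and 3, and 4, 4 and 4 without KO IRI 1, 2 and 3. It was 28 (15 higher, 13 lower, 1 shared) without the 3 libraries that stand apart.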

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

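The tests of scaling, background, cell makeup and position below, the split count for the rescaled values, and the look at which libraries a split exchanges, were chosen only after the results were seen, while the other split counts were planned.

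The difference between genotypes in the effect of IRI passed the threshold for 1 gene, the small nucleolar RNA Gm25744 (chromosome 17, 34952013 to 34952075; log2 −7.98 ± 0.74, adjusted p = 0.00844), which read 744, 109.5 and 195 FPKM in KO controls. By camera it passed for the T cell activation (adjusted p = 0.019), trafficking receptor (0.0267), Th1 (0.0381), interferon stimulated (0.0335), heat shock (0.00226), T cell identity (0.000463) and loop and distal tubule (0.0208) lists, placed higher, and for the macrophage and monocyte (0.000463), dendritic cell (0.000763) and B cell (0.00263) lists, placed lower. None of these lists passed with an estimated correlation (adjusted p = 0.871 each) or by fry (0.900 each). With each library scaled to a common sum, the medians of the T cell activation, trafficking, Th1, interferon and T cell identity lists turned below 0, as did that of all genes (−0.335), and these lists were no longer called, nor was the loop and distal tubule list after quantile normalization (0.0839). Of 100 splits of the 12 libraries, 61 gave at least 1 gene in this test, with at most 7 in another split, so chance cannot be excluded for Gm25744.

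Many more genes were higher than lower in KO averaged over condition (2299 against 340), an imbalance also seen at an unadjusted p under 0.05 (83.1% higher of 7139 genes). After median-ratio rescaling 48.7% of 4125 such genes were higher, but this rescaling itself sets the median gene near 0, so a difference in scaling between the deposited libraries and a rise of most genes in KO cannot be told apart. The genes called higher had a median log2 of 0.647 ± 0.158 (median SE) as deposited and 0.349 ± 0.125 rescaled, and all 2299 stayed above 0. In proportion the median change shrank more than the median SE, while why single calls ended was not tested gene by gene. A lower background from across the genome in KO libraries could raise all other genes, and with the receptor level as a covariate the median of all genes was 0.113 against 0.292 without it, but the receptor level goes with genotype, so the background cannot be told apart from it. In the split counts 1 of 100 splits, the real one, gave as many genes as deposited (2639, highest other 6) and 1 of 100 after rescaling (106, highest other 6). This is the smallest share that 100 splits can give, and it argues against a chance split of the libraries for these counts. The source of the mice stays open.

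T cell identity genes were lower after IRI (averaged over genotype, adjusted p = 5.68e-11 by camera and 0.246 with an estimated correlation). A lower share of T cells, with the mix of other cells unchanged, would raise the markers of all other cells alike. Neutrophil and B cell scores moved apart by a log2 of 2.56 (exact p = 0.005 over 400 shuffles within genotype, the smallest they can give). That argues only against an unchanged mix, and the p adds little because the 2 lists were picked after their directions were known. A lower share of T cells beside a changed mix of other cells stays open. Scaling is argued against by a list median of −0.743 after rescaling, with 18 of 19 members below 0. Naive genes gained on Th1 genes by a log2 of 1.17 (exact p = 0.005), but naive genes themselves stood at −0.00787 (exact p = 0.935), so this restates the Th1 fall and leaves open a changed makeup of the CD4 T cells, arriving cells, cell loss and lower expression per cell. Of the 100 splits averaged over genotype 1, the real one, gave as many genes (1744). This is the smallest share that 100 splits can give, and it argues against a chance split. The highest other (1038) exchanged KO control 2 and KO IRI 1, while 4 other exchanges of 1 pair of KO libraries gave at most 2 genes. Zfp683 goes with the labels of KO control 2 and KO IRI 1 (25.9 and 1.66 FPKM), but it was called with these same labels. List means of KO control 2 and KO IRI 1 pointed both ways, at 24.7 and 7.96 FPKM for B cell genes and 56.3 and 59.6 for trafficking receptors. Injured tubule genes averaged 1.98 FPKM in KO IRI 1, against 29.6 and 34.1 in KO IRI 2 and 3. What else sets KO control 2 and KO IRI 1 apart stays open.

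Among genes called in KO after rescaling, 4 of 8 tested genes between 60 and 61 Mb of chromosome 3 were higher: Mbnl1, Gm33707, Gm38326 and Tgif1-ps. A window of 1 Mb with as many called genes occurred in a share of 0.027 of 1e+05 shuffles of 106 positions, which argues against placement by such shuffles, though these ignore that genes of 1 family lie together, as 4 others called here (Klrc1, Klrc2, Klrk1 and Klre1 on chromosome 6) do. The 26 tested genes within 2 Mb of Mbnl1, the 4 included, had a median log2 of 0.16, with an SD between genes of 0.982. The genes other than the 4 ran from −1.717 (Gm37404) to 0.8244 (Gm22491). None reached the smallest change of the 4 (0.83), but the 4 were picked as called genes. The median lay below 0.83 by less than the SD, so these values cannot decide on a rise of that size across the whole segment. A smaller or partial change stays open as well. Further called genes of chromosome 3 started outside this window, Gm43516 at 66953541 and Trim59 at 69035288 (rescaled 1.01 ± 0.13, adjusted p = 0.0182). Gm15535 started at 85556046 and Gm37361 at 93100466. A segment or variant carried along with the KO line may be the source and was not tested, since it goes with genotype as the loss of Keap1 does. Reads of the source gene Tgif1 (rescaled 0.53 ± 0.15, adjusted p = 0.0927) could also be assigned to its pseudogene, which was not tested.

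For the comparisons of 3 libraries with 3, the 10 splits are too few to exclude chance. The real split gave 729 genes for WT IRI against WT control (highest other 6, 1 of 10 splits as large), 167 for KO IRI against KO control (5, 1 of 10), 11 for KO IRI against WT IRI (5, 1 of 10) and 5 for KO control against WT control (28, 3 of 10).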

How the results depend on the processing

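Alternatives chosen only after the data were seen were leaving out the 3 libraries that stand apart, the receptor covariate, protein-coding genes only, and leaving out libraries for list counts. Counts are given for WT IRI (729), KO IRI (167), KO control (5), KO IRI against WT IRI (11), the interaction (1), IRI averaged (1744) and KO averaged (2639), and those not given stayed within 1.5 times; except where fewer genes, libraries or groups entered, the cause was not tested. A pseudocount of 0.1 gave 10 for KO control, and a pseudocount of 5 gave 3 for KO control, 0 for KO IRI against WT IRI and 0 for the interaction. No minimum gave 405, 78, 3 (interaction), 1081 (IRI averaged) and 211 (KO averaged), and a minimum of 5 gave 81 for KO IRI against WT IRI. Quantile normalization gave 1767, 327, 2644 (IRI averaged) and 54 (KO averaged), median-ratio rescaling 1531, 398, 2639 and 106, and a common sum 104, 52, 3 (KO control), 0 (KO IRI against WT IRI), 1006 and 13. Without the trend the counts were 109 (KO IRI) and 1621 (KO averaged), with robust moderation 42 (KO IRI against WT IRI), and with library weights 2242, 2764, 6356, 817, 4603 (IRI averaged) and 7335 (KO averaged). Only the groups compared gave 403 and 8, with 0 of the 8 among the 167, and the 5 for KO control and 9 for KO IRI against WT IRI also shared 0 genes with the 5 and 11 first called. Without the 3 libraries that stand apart the counts were 224, 40, 31, 19, 28, 1068 and 54. The receptor covariate gave 12 (KO IRI), 3 (KO control), 1 (KO IRI against WT IRI), 643 and 4, and protein-coding genes only 1169, 552, 38, 551, 0 and, for KO averaged, 4185. Leaving out 1 library gave 255 to 917, 44 to 848, 4 to 1961, 0 to 552, 2 to 12, 1044 to 2615 and 34 to 5898. The replicate number as a block gave 3 for KO IRI against WT IRI and 1687 for KO averaged, and moved no other count by over 1.5 times (549, 143, 4, 1 and 1547). Whether the numbers pair the libraries cannot be told. About their group means, the 18 same-numbered pairs between groups correlated at −0.0371 to 0.202 (mean 0.0329, 1 over 0.1). The 36 pairs of different number correlated at −0.147 to 0.119 (mean −0.0164, 1 over 0.1). Of the 12 libraries, 7 correlated best with their own number. This small lean towards pairing was not tested against chance. Of the lists called (17, 16, 15, 18, 10, 16 and 17 of 28), 0 in each comparison passed with an estimated correlation, fry called 6, 9 and 8 in the first 3 comparisons and 0 in the interaction, and rescaling by median ratios 9 in KO control. Over all 109 called lists 65 kept their call by fry, 100 after median-ratio rescaling, 109 with the block and 109 with a pseudocount of 0.1, and 0 turned. Quantile normalization kept 85 and a common sum 89, with 2 and 12 medians across 0, and the direction of 1 list turned, immediate early genes in KO control after quantile normalization (median −0.0428, not called). Leaving out 1 library gave 12 to 18, 14 to 18, 9 to 18, 16 to 19, 4 to 11, 15 to 17 and 15 to 20 lists. Of the genes named, 20 of 69 called in WT IRI and 60 of 99 in IRI averaged kept their call and direction under every alternative, against 0 of 50 in KO IRI, 0 of 5 in KO control, 0 of 8 in KO IRI against WT IRI and 0 of 98 in KO averaged, and no called gene turned. Among genes not called, a common sum turned Nfe2l2 (−0.07) and Hmox1 (−0.09) in KO IRI against WT IRI and, in the interaction, Keap1 (−0.22), Txnrd1 (−0.36), Srxn1 (−0.15), Hmox1 (−0.37) and Slc7a11 (−0.18), where the median of all genes stood lower (−0.265 and −0.335) except for Txnrd1 and Hmox1 in the interaction. There, library weights turned Keap1 (−0.14), Txnrd1 (−0.20), Srxn1 (−0.18) and Hmox1 (−0.29), quantile normalization Srxn1 (−0.07) and Hmox1 (−0.15), a pseudocount of 0.1 Hmox1 (−0.04), the receptor covariate Nfe2l2 (0.24) and Slc7a11 (−0.01), and leaving out the 3 libraries Keap1 (−0.03), Srxn1 (−0.46) and Hmox1 (−0.36). Leaving out 1 library gave ranges across 0 for Nfe2l2 (−0.31 to 0.15), Txnrd1 (−0.16 to 0.29), Srxn1 (−0.57 to 0.62) and Hmox1 (−0.31 to 0.28). FPKM holds no counts, so the limit set by depth is unknown.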

Other observations

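Nothing below was planned, and all genes here were chosen after their values were seen. The values below are KO against WT averaged over condition after rescaling, and no list of innate-like T cell genes was tested. Zbtb16, which encodes PLZF, a regulator of innate-like T cells, fell by a log2 of 1.26 ± 0.20 (SE, n = 6; adjusted p = 0.0297), and all 6 WT libraries lay above every KO library. The T cell receptor gamma genes Tcrg-C1 (−1.34 ± 0.21, 0.0318), Trgv2 (−1.34 ± 0.19, 0.0272) and Tcrg-V4 (−1.25 ± 0.22, 0.0457) also fell, with 3, 4 and 1 of 6 WT libraries above every KO library, while the delta constant gene Trdc (0.18 ± 0.20, 0.633) and Cd1d1, whose product presents lipids (0.38 ± 0.17, 0.233), did not pass. Fgl2, a secreted regulator, fell by 1.34 ± 0.15 (0.0061).

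Higher in KO were Gzmk, a granule protease (1.83 ± 0.23, adjusted p = 0.0116), Cpt1a, which brings fatty acids into mitochondria (0.82 ± 0.12, 0.0296), and the receptor segment Trbv31 (1.02 ± 0.12, 0.0116). Reads of T cell receptor segments of 1 family can be hard to tell apart.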
